A study of Homo sapiens with 20 samples.

How the data were processed

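Total RNA and ribosome footprints of P493 cells with and without tetracycline were read from gene count tables, and the libraries with HR in their titles from a pair of further count tables. Counts per Ensembl gene were used as deposited by the authors. Reads were aligned with STAR to GRCh37, per the submitters' processing notes, which give no version, and the counter and annotation release are not given in the sources used here. The strand of counting is not stated either, so values of overlapping and antisense genes, and of near-identical copies such as histones, ribosomal proteins and mitochondrial genes, are uncertain. The log2 values in the table of translational efficiency are changes in translational efficiency, mRNA and footprints of myc- over myc+, computed by the authors with RiboDiff per the file headers and name. The ratio of footprints to mRNA in each condition was also computed by the authors. The adjusted p-values of that table were computed by the authors, with a method of adjustment that is not stated. The score of each predicted ORF is a fraction of at least 0.8 made by the authors with a caller that is not named, and start and stop positions on the transcript are as deposited by the authors. The word sim in some deposited names is not explained.

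Genes were compared with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and the robust quasi-likelihood F-test. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. RNA compared 2 treated with 2 untreated libraries, footprints 3 with 3, and translational efficiency was the interaction of assay and treatment over these 10 libraries. In the MycNeg and MycPos tables HarPos was compared with HarNeg within each table, since titles and column names conflict. In MycNeg, HarPos columns belong to titles with plus_HR and HarNeg to plus_HR_RF, while MycPos has the opposite, and the sample titled P493_2_plus_HR is described as Rep3. The 27 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry, and members were also adjusted over the list alone. Overlaps are given with the number expected if calls were independent. Shares of ORFs were compared with Fisher's exact test, two-sided, and permutation tests used 100000 resamples.

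Genes were named by a rule: MYC always, then the 10 highest and 10 lowest log2 changes among genes that passed with a mean of at least 10 CPM (in both assays for translational efficiency) and groups that did not overlap in RNA or footprints, then up to 4 passing members of each list with the largest change. Immunoglobulin genes and pseudogenes were left out of the 10 and 10, and 5 and 5 were named in the MycNeg and MycPos tables. Groups, comparisons, lists, this rule and most alternatives were set before the data were examined. Of 57905 genes, 20356 were named by the authors' table, 20559 by GENCODE 29 and 16990 had no name. GENCODE 29 is on GRCh38 and was used for names, biotypes, lengths and transcript sequences. ORFs with identical coordinates were merged.

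The fits were tested on simulated data with 100 changed genes at each fold change. Changed genes had a mean of at least 10 CPM, all others were unchanged, and genes varied independently. At 2-fold the fits found 100% of changed genes in RNA, 75% in footprints and 80% in translational efficiency. At 4-fold they found 100% in each, with 4.31%, 4.89% and 5.26% false calls among all calls. These rates do not carry over to genes of lower level or to data with many more changed genes. Footprint libraries held 897959 to 5081203 counts and RNA libraries 109558537 to 178750090. Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a stricter filter of 5 CPM, a joint fit over 4 groups, a block for replicate number, a minimum log2 change of 1 and leaving out each library. Alternatives added later were protein-coding genes alone, thinning of the untreated RNA libraries, an offset for coding length, the interaction of HarPos with the table and removal of the most abundant feature. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 handled ORFs and figures.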

Results

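Gene expression and translation were measured in P493 cells, a human B-cell line that carries a MYC transgene which tetracycline turns off. Cells received 0.1 µM tetracycline over 24 hours or were left untreated, and cycloheximide, which holds cytosolic ribosomes in place on the mRNA, was added for 10 minutes. One aliquot gave total RNA and the rest gave ribosome footprints, the stretches of mRNA that ribosomes shield from nuclease. Of the 20 libraries, 2 untreated and 2 tetracycline-treated libraries held RNA, and 3 untreated and 3 treated libraries held footprints. The other 10 libraries carry HR in their titles and are described after the main comparison. Total counts were 157991007 and 178750090 in the untreated RNA libraries and 109558537 and 115326532 in the treated ones. The footprint libraries were far smaller, at 3953628, 897959 and 3443289 counts without the drug and 4365633, 3877217 and 5081203 with it. Libraries of both groups also differed in what they held. The mitochondrial ribosomal RNA MT-RNR2 took 34.0%, 29.6% and 31.9% of the untreated footprint counts and 14.6%, 18.4% and 17.0% of the treated ones. Protein-coding genes took 61.5% and 61.4% of untreated RNA counts against 66.1% and 65.8% of treated ones, and 40.2%, 36.3% and 47.0% of untreated footprint counts against 57.9%, 53.1% and 54.7%. At least 1 count was found for 48065 and 50206 genes in untreated RNA and for 31483 and 32189 genes in treated RNA. The design text speaks of triplicates without saying that replicates were separate cultures, so p-values here measure the spread between these libraries, which may be technical.

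The first question was how far MYC itself fell. MYC (ENSG00000136997), a transcription factor that drives growth and division, stood at 459.9 and 458 CPM (counts over library totals after TMM scaling) in untreated RNA and at 404 and 404 CPM after tetracycline. That is 0.880 times the untreated level (log2 change −0.19, SE 0.0345, edgeR adjusted p = 0.000131). With TMM scaling within each assay, footprints on MYC fell further, from 506 ± 101 CPM (SD, n = 3) to 312 ± 24.0 CPM (n = 3), or 0.618 times (log2 change −0.69, SE 0.142, adjusted p = 0.0012). Every treated library lay below every untreated one in both assays. Without TMM scaling the footprint values were closer, at 446, 457 and 412 CPM untreated and 334, 365 and 350 CPM treated. RNA without TMM scaling stood at 470 and 469 CPM untreated and 395 and 393 CPM treated. How much further footprints fell than RNA thus depends on scaling. The translational efficiency of MYC, its footprints relative to its RNA, had a log2 change of −0.26 (SE 0.186, adjusted p = 0.434), which did not pass the test. That test scaled RNA and footprint libraries together, where MYC changed by −0.36 in RNA and −0.63 in footprints. The −0.26 is thus not the difference of the changes above, which come from scaling within each assay. Counts per gene do not separate transgene transcripts from those of the cell's own MYC gene. The RNA call was lost in a joint fit of RNA and footprints that shares their spread (log2 change −0.36, adjusted p = 0.0657).

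**Figure D1:**
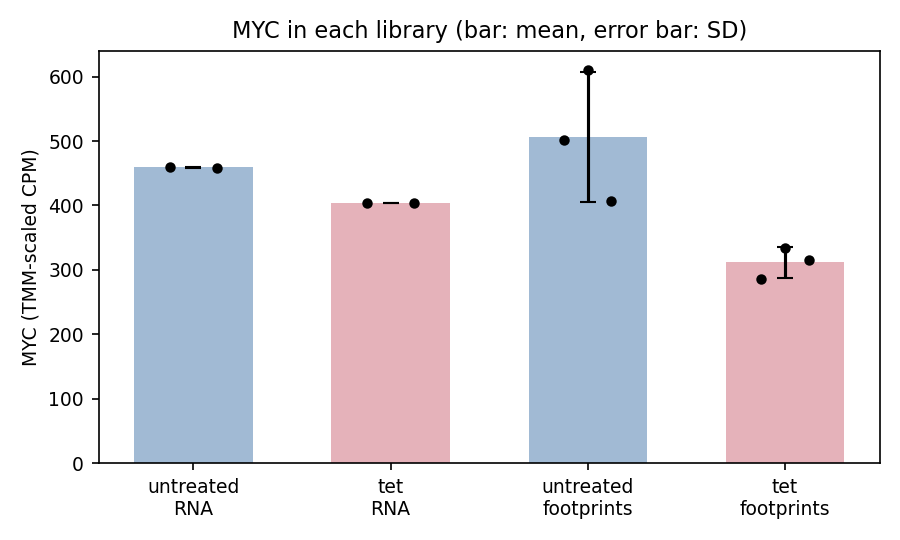
MYC level in TMM-scaled CPM in untreated and tetracycline-treated libraries, for RNA on the left (n = 2 and 2) and footprints on the right (n = 3 and 3); bars are group means with SD and points are single libraries. Treated libraries sit below untreated ones in both assays, with means of 404 against 459 CPM in RNA and 312 against 506 CPM in footprints.

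The RNA libraries show which transcripts changed after tetracycline. Rises and falls here and below are relative to the other genes of a library, since scaling does not measure RNA per cell. Genes of cell division and DNA synthesis rose. KIF20A (ENSG00000112984), a kinesin of cytokinesis, went from 27.9 ± 0.643 to 85.5 ± 0.861 CPM (SD, n = 2 and 2), which is 3.07-fold (log2 change 1.62, SE 0.0448, adjusted p = 2.22e-16). DLGAP5, a spindle protein, rose 3.08-fold from 68.0 ± 1.24 to 209 ± 10.5 CPM. The nuclear noncoding RNA NEAT1 fell from 232 ± 22.2 to 84.4 ± 3.79 CPM (log2 change −1.46, SE 0.0537, adjusted p = 5.23e-13). All 30 mitosis genes rose (30 adjusted over the list alone), with a median log2 change of 1.20. Among them were HMMR (log2 1.51), the B-type cyclin CCNB2 (log2 1.49) and the mitotic kinase PLK1 (log2 1.42). The 34 measured DNA replication genes all rose as well (34 adjusted over the list alone, median 0.79), including the primase subunit PRIM1 (log2 1.31), the ligase LIG1 (log2 1.15) and the clamp loader subunit RFC3 (log2 1.05). All 27 measured histone genes rose (27 adjusted over the list alone, median 1.13), for example HIST1H4A (log2 1.45), HIST1H2AB (log2 1.34) and HIST1H3H (log2 1.33). Histone genes are near-identical copies, so counts of single members are uncertain. Camera, which compares a list with all other genes at a preset correlation, gave adjusted p = 5.6e-78 for mitosis, 1.16e-55 for replication and 2.94e-76 for histones. With an estimated correlation the calls were lost, at adjusted p = 0.108, 0.108 and 0.113.

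Metabolic and biosynthetic transcripts mostly rose. Of 30 purine, pyrimidine and one-carbon enzymes, 24 rose and 1 fell (24 and 1 adjusted over the list alone, median 0.40, camera adjusted p = 2.74e-19, adjusted p = 0.121 with an estimated correlation). Examples are thymidine kinase TK1 (log2 1.24) and the ribonucleotide reductase subunit RRM1 (log2 1.15). Nuclear genes of oxidative phosphorylation rose in 73 of 77 cases and fell in none (74 and 0 adjusted over the list alone, median 0.35, adjusted p = 1.21e-26, adjusted p = 0.108 with an estimated correlation), for instance NDUFA6 (log2 0.71) and COX8A (log2 0.61). In the tricarboxylic acid cycle 20 of 23 genes rose and 1 fell (21 and 1 adjusted over the list alone, median 0.34, adjusted p = 2.43e-10, adjusted p = 0.108 with an estimated correlation), with isocitrate dehydrogenase IDH2 at log2 1.15 and fumarase FH at 0.63. Glycolysis genes rose in 16 of 21 cases and fell in 2 (17 and 2 adjusted over the list alone, median 0.37, adjusted p = 5.76e-10, adjusted p = 0.183 with an estimated correlation), among them GAPDH (log2 0.62) and ENO1 (log2 0.60). Among mitochondrial ribosomal proteins 68 of 76 rose and 1 fell (70 and 1 adjusted over the list alone, median 0.29, adjusted p = 1.88e-17, adjusted p = 0.108 with an estimated correlation), such as MRPS18B (log2 0.63). The 13 proteins encoded by mitochondrial DNA went the other way, and all 13 fell (13 adjusted over the list alone, median −0.66, adjusted p = 2.91e-17, adjusted p = 0.183 with an estimated correlation). MT-ND4, a subunit of complex I, fell from 916 to 452 CPM (log2 −1.02, SE 0.039), and MT-RNR2 took 21.6% and 23.0% of untreated against 16.7% and 16.6% of treated RNA counts. In the joint fit with footprints 11 of 77 oxidative phosphorylation genes, 9 of 76 mitochondrial ribosomal proteins and 4 of 23 tricarboxylic acid cycle genes rose. So did 6 of 19 glycolysis genes and 12 of 30 nucleotide enzymes. Of the 13 mitochondrial genes 11 fell. Upper-quartile scaling gave 66 up and 2 down, 45 and 2, 14 and 2, 13 and 2 and 19 and 5 for the same 5 nuclear lists.

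Genes of RNA processing, protein folding, stress responses and amino acid supply mostly rose. Splicing factors rose in 32 of 38 cases with none lower (33 and 0 adjusted over the list alone, median 0.27, adjusted p = 7.54e-12, adjusted p = 0.183 with an estimated correlation), among them HNRNPL (log2 0.61). For aminoacyl-tRNA synthetases, which charge tRNAs, 18 of 22 rose and none fell (18 and 0 adjusted over the list alone, median 0.33, adjusted p = 5.29e-10, adjusted p = 0.202 with an estimated correlation), with WARS at log2 0.85. Of 25 integrated stress and unfolded protein response genes, 17 rose and 3 fell (18 and 3 adjusted over the list alone, median 0.54, adjusted p = 3.32e-09, adjusted p = 0.385 with an estimated correlation). Its named members PHGDH (log2 1.29), PSAT1 (log2 1.02) and ASNS (log2 0.82) make serine and asparagine, and TRIB3 (log2 0.78) is a pseudokinase. Chaperones rose in 19 of 25 cases and fell in 3 (20 and 3 adjusted over the list alone, median 0.23, adjusted p = 7.36e-06, adjusted p = 0.455 with an estimated correlation), from HSP90AA1 (log2 0.49) to HSPA1B (log2 −0.60), a near copy of HSPA1A. Amino acid transporters rose in 9 of 13 cases and fell in 2 (10 and 2 adjusted over the list alone, median 0.24, adjusted p = 0.00657, adjusted p = 0.385 with an estimated correlation), with SLC1A4 at log2 0.48 and SLC7A6 at −0.48. In the joint fit with footprints these counts were far lower, at 2 up of 38 splicing factors, 3 of 22 synthetases and 11 up and 2 down of 24 stress-response genes. Chaperones and amino acid transporters had 0 up and 1 down each by edgeR. Upper-quartile scaling gave 21 up and 5 down for splicing factors, 14 and 2 for synthetases, 13 and 5 for stress-response genes, 12 and 5 for chaperones and 7 and 3 for transporters.

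Transcripts known as MYC targets did not follow MYC downward. Of 36 canonical targets, 27 rose and 3 fell (28 and 3 adjusted over the list alone, median 0.26, adjusted p = 6.48e-12, adjusted p = 0.16 with an estimated correlation), including the cell-cycle regulators E2F2 (log2 1.13) and E2F1 (log2 0.79) and the telomerase gene TERT (log2 0.93). Among 27 growth-arrest genes 7 rose and 11 fell (7 and 11 adjusted over the list alone, median −0.12, adjusted p = 0.199). The cyclin-dependent kinase inhibitor CDKN1A fell from 49.0 ± 1.62 to 24.5 ± 1.98 CPM (adjusted p = 2.56e-12) and the antiproliferative factor BTG1 fell by 0.99 on the log2 scale, while another inhibitor, CDKN2C, rose (log2 0.75). Several lists had small medians whose direction depended on scaling. Under upper-quartile scaling, which shifts the median of all genes by −0.13, the medians turned from 0.08 to −0.05 for cytosolic ribosomal proteins, from 0.13 to −0.00 for translation factors and from 0.08 to −0.06 for ribosome biogenesis. They also turned from 0.05 to −0.08 for the B cell list, from 0.05 to −0.08 for the interferon list and from 0.05 to −0.08 for apoptosis regulators. With the main scaling 38 of 79 cytosolic ribosomal proteins rose and 3 fell (38 and 3 adjusted over the list alone, adjusted p = 0.00349, adjusted p = 0.657 with an estimated correlation), with RPS2 at log2 0.36. The median of all genes at 10 CPM or more was 0.14, above that of this list, so its camera call does not set it above such genes. Translation factors rose in 30 of 47 cases and fell in 3 (31 and 3 adjusted over the list alone, adjusted p = 0.000317, adjusted p = 0.252 with an estimated correlation), with EIF2S2 at log2 0.55 and EIF5B at −0.55. For ribosome biogenesis 23 of 55 rose and 11 fell (26 and 11 adjusted over the list alone, adjusted p = 0.093), with TCOF1 at log2 0.43 and the RNA polymerase I subunit POLR1A at −0.46. With a block for replicate number this list passed camera upward (adjusted p = 0.0295). Under that scaling 6 cytosolic ribosomal proteins rose and 23 fell, and 8 ribosome biogenesis genes rose and 21 fell. Translation factors had 12 up and 10 down, and MYC targets 19 and 6. The joint fit with footprints called 0 of 78 cytosolic ribosomal proteins by edgeR, 1 up and 3 down of 46 translation factors, 0 and 4 of 55 ribosome biogenesis genes and 6 and 1 of 35 MYC targets.

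Lymphocyte, immune and lipid genes moved in both directions. In the B cell list 18 of 42 rose and 11 fell (19 and 11 adjusted over the list alone, adjusted p = 0.093). The surface protein CD20, encoded by MS4A1, rose from 144 ± 1.38 to 291 ± 14.5 CPM (log2 1.02), and the chemokine receptor CCR7 fell by 0.97 on the log2 scale. Antigen presentation genes rose in 10 and fell in 9 of 29 cases (10 and 9 adjusted over the list alone, median −0.00, adjusted p = 0.739), with the proteasome subunit PSMB9 at log2 0.61 and ICAM1 at −0.49. NF-kappa-B targets rose in 9 and fell in 10 of 28 cases (9 and 10 adjusted over the list alone, median −0.03, adjusted p = 0.391). Interferon genes rose in 17 and fell in 11 of 40 cases (17 and 11 adjusted over the list alone, adjusted p = 0.271), with OAS3 at log2 0.76 and STAT2 at −0.92. Apoptosis regulators rose in 9 and fell in 5 of 23 cases (9 and 5 adjusted over the list alone, adjusted p = 0.64), with BCL2L11 at −0.55. Of 29 lysosome and autophagy genes 5 rose and 13 fell (5 and 13 adjusted over the list alone, median −0.08, adjusted p = 0.0594), with the peptidase TPP1 at −0.94. Cholesterol synthesis and uptake genes fell in 12 of 21 cases and rose in 2 (12 and 2 adjusted over the list alone, median −0.26, adjusted p = 0.00301, adjusted p = 0.183 with an estimated correlation), among them LSS (log2 −0.77) and HMGCS1 (log2 −0.63). Markers of other cell types fell in 13 of 17 cases and rose in none (13 and 0 adjusted over the list alone, adjusted p = 0.00295, adjusted p = 0.202 with an estimated correlation). Nearly all were of low level, where background in the untreated RNA libraries could not be excluded. Among these markers CD4 was the one with at least 10 CPM, at 28.2 ± 1.38 and 25.3 ± 0.61 CPM (log2 −0.16, adjusted p = 0.0199), a call that ended without untreated RNA library 1 or treated RNA library 1. Under upper-quartile scaling more of these immune and lipid genes were called down, with 11 up and 17 down in the B cell list, 3 and 16 in antigen presentation (median −0.14) and 2 and 12 among NF-kappa-B targets (median −0.16). Interferon genes had 14 and 17, apoptosis regulators 2 and 8, lysosome genes 1 and 16 and cholesterol genes 2 and 17. In the joint fit with footprints the counts were 4 and 8, 2 and 6, 0 and 6, 7 and 7, 1 and 3, 0 and 12 and 0 and 11 in the same order.

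Across all 27963 genes tested in RNA, 6420 rose, 7826 fell and 13717 did not pass at an adjusted p of 0.05. With the main scaling the direction depended on the level of the gene. At a mean of 10 CPM or more, 4641 genes rose and 1210 fell (median log2 change 0.14), while under 10 CPM 1779 rose and 6616 fell (median −0.34). Camera compares a list with tested genes of every level, so its calls do not separate a list from genes of like level. Of the 5157 genes that fell by at least 2-fold, 5145 were under 10 CPM, and fitted changes of genes with few counts depend on the prior of the fit. Background in the untreated RNA libraries could not be told apart from lower transcription for these genes. Upper-quartile scaling gave 3902 genes up and 10448 down in place of 6420 and 7826. A stricter filter called 6448 genes, 4733 of them also called above. It gave 3199 up and 3249 down, but TMM was recomputed on the genes it kept, which centres their changes near 0. This split therefore cannot show whether genes of higher level mostly rose. The joint fit with footprints called 3714, of which 3221 were called above. Camera called 16 lists up and 3 down of 27, and 0 of 27 with an estimated correlation. Fry, which asks whether a list moves one way without comparing it with other genes, called 18.

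**Figure D2:**
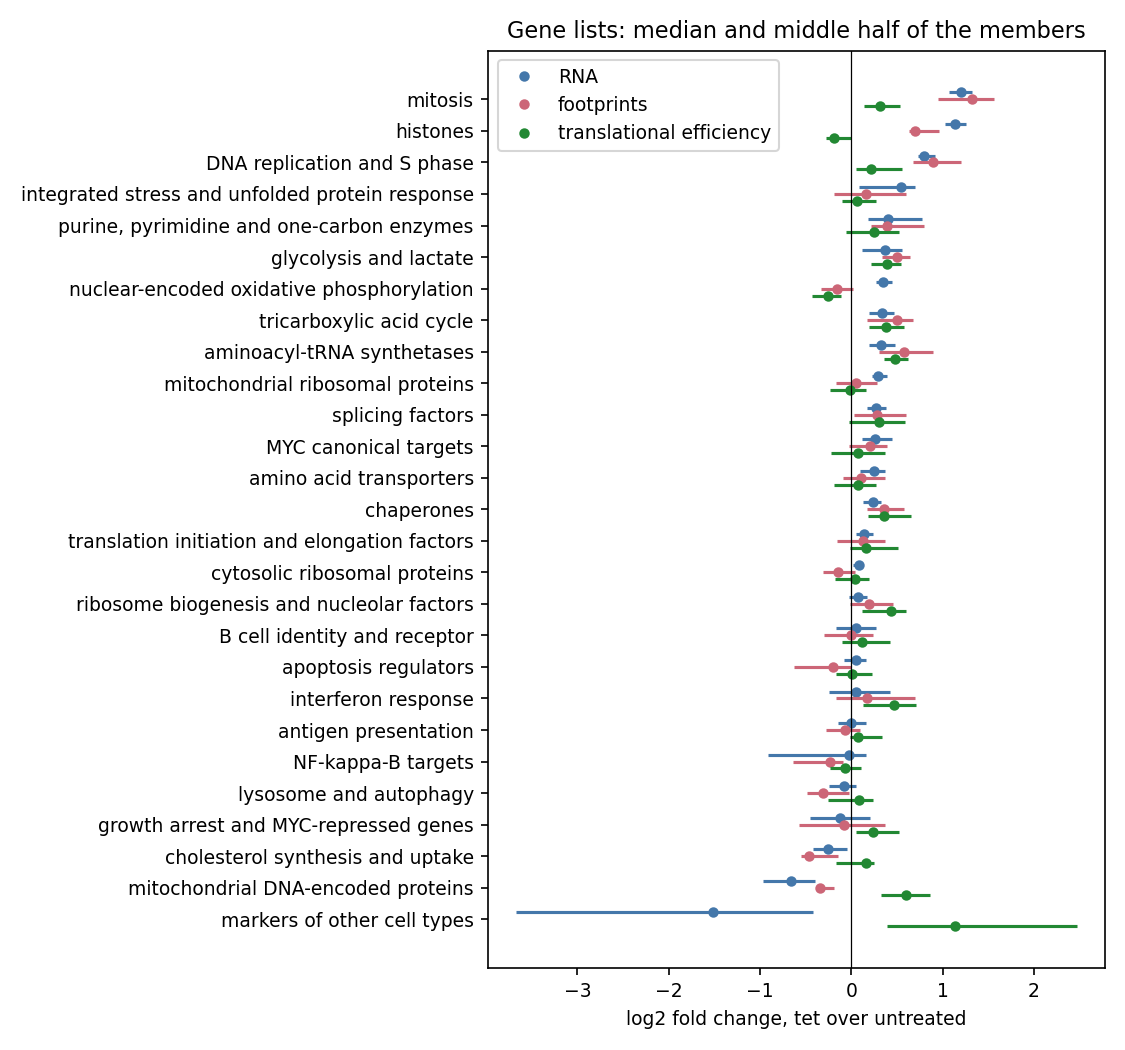
Median log2 change (tetracycline over untreated) of each of the gene lists in RNA, footprints and translational efficiency; bars span the middle 50% of members. Mitosis has the highest RNA median, at 1.20, and proteins encoded by mitochondrial DNA stand at −0.66 in RNA and 0.60 in translational efficiency; cytosolic ribosomal proteins turn from 0.08 to −0.05 in RNA under upper-quartile scaling, as do other lists near 0.

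Footprints show which mRNAs ribosomes occupied more or less after tetracycline. Cell division again rose most among the lists. Cyclin B1 (CCNB1, ENSG00000134057), which starts mitosis, went from 63.5 ± 14.9 to 262 ± 21.2 footprint CPM (SD, n = 3 and 3), 4.06-fold (log2 change 2.02, SE 0.159, adjusted p = 8.34e-09). The nucleolar protein TCOF1 rose from 39.0 ± 8.48 to 116 ± 10.1 CPM (log2 1.51, SE 0.153, adjusted p = 2.01e-07). In the mitosis list 27 of 30 rose and none fell (27 and 0 adjusted over the list alone, median 1.32), with HMMR at log2 2.15 and the spindle factor TPX2 at 1.91. DNA replication genes rose in 27 of 34 cases with none lower (30 and 0 adjusted over the list alone, median 0.89), such as the origin protein ORC1 (log2 1.90) and the helicase subunit MCM4 (log2 1.52). Histones rose in 26 of 27 cases with none lower (27 and 0 adjusted over the list alone, median 0.70), with the linker histone HIST1H1D at log2 1.58. Camera gave adjusted p = 1.42e-40, 5.85e-26 and 1.35e-14 for these 3 lists, and adjusted p = 0.0509, 0.249 and 0.309 with an estimated correlation. Genes called higher in both assays numbered 926 of 11152 tested in both, against 542 if the calls were independent, and genes called lower in both 308 against 102.

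Several metabolic and biosynthetic lists passed camera upward in footprints, though many of their genes did not pass singly. Purine, pyrimidine and one-carbon enzymes rose in 13 of 30 cases and fell in 1 (18 and 2 adjusted over the list alone, median 0.39, adjusted p = 8.79e-07, adjusted p = 0.303 with an estimated correlation), with RRM1 at log2 1.70 and thymidylate synthase TYMS at 1.15. Aminoacyl-tRNA synthetases rose in 13 of 22 cases with none lower (16 and 0 adjusted over the list alone, median 0.58, adjusted p = 7.42e-07, adjusted p = 0.309 with an estimated correlation), with AARS at log2 1.12. The tricarboxylic acid cycle had 14 of 23 higher and none lower (15 and 0 adjusted over the list alone, median 0.50, adjusted p = 1.94e-06, adjusted p = 0.309 with an estimated correlation), and glycolysis had 11 of 19 higher and none lower (15 and 0 adjusted over the list alone, median 0.50, adjusted p = 2.26e-05, adjusted p = 0.309 with an estimated correlation). Splicing factors rose in 16 of 38 cases and fell in 1 (17 and 2 adjusted over the list alone, median 0.28, adjusted p = 0.000892, adjusted p = 0.309 with an estimated correlation), with HNRNPL at log2 1.20. Ribosome biogenesis factors rose in 15 of 55 cases and fell in 2 (15 and 2 adjusted over the list alone, median 0.19, adjusted p = 0.000987, adjusted p = 0.376 with an estimated correlation), and nucleolin, NCL, a nucleolar RNA-binding protein, stood at log2 1.39. Chaperones rose in 12 of 24 cases with none lower (14 and 0 adjusted over the list alone, median 0.35, adjusted p = 0.00264, adjusted p = 0.519 with an estimated correlation), with HSP90AA1 at log2 1.04. Stress-response genes rose in 5 of 23 cases with none lower (5 and 0 adjusted over the list alone, median 0.16, adjusted p = 0.0174, adjusted p = 0.309 with an estimated correlation), with PHGDH at log2 1.47. MYC targets rose in 8 of 35 cases with none lower (9 and 2 adjusted over the list alone, median 0.20, adjusted p = 0.034, adjusted p = 0.525 with an estimated correlation), a list call that ended without untreated footprint library 1 or treated footprint library 1.

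The lysosome and cholesterol lists passed camera downward, with most of their genes not passing singly. Lysosome and autophagy genes fell in 6 of 29 cases and rose in none (6 and 0 adjusted over the list alone, median −0.31, adjusted p = 0.00942, adjusted p = 0.309 with an estimated correlation), with the cathepsin CTSZ at log2 −1.04 and MAP1LC3B at −0.99. Cholesterol genes fell in 6 of 20 cases and rose in 1 (7 and 1 adjusted over the list alone, median −0.46, adjusted p = 0.00565, adjusted p = 0.309 with an estimated correlation). Both of these list calls ended without untreated footprint library 3. Growth-arrest genes rose in 3 and fell in 7 of 25 cases (4 and 7 adjusted over the list alone, median −0.08, adjusted p = 0.243), with BTG2 at log2 −1.04 and CDKN1A at −0.96. In the B cell list 4 of 37 rose and 4 fell (6 and 4 adjusted over the list alone, median −0.00, which is 0.01 under RLE scaling, adjusted p = 0.656), with the adaptor BANK1 at log2 1.72 and CCR7 at −1.04. Cytosolic ribosomal proteins rose in 4 and fell in 10 of 78 cases (4 and 10 adjusted over the list alone, median −0.14, adjusted p = 0.113), with RPL6 at log2 0.72 and RPL22 at −0.80. Nuclear oxidative phosphorylation genes rose in 7 and fell in 10 of 77 cases (9 and 13 adjusted over the list alone, median −0.15, adjusted p = 0.165), with SDHA at log2 1.00 and UQCR11 at −0.82. Of the proteins encoded by mitochondrial DNA 4 of 13 fell and none rose (7 and 0 adjusted over the list alone, median −0.35, adjusted p = 0.111). Without untreated footprint library 2, the smallest, this list and the cytosolic ribosomal proteins passed camera downward (adjusted p = 0.00132 and 0.0128). The remaining lists did not pass camera. Their counts up and down were 7 and 3 of 76 mitochondrial ribosomal proteins, 8 and 1 of 45 translation factors, 2 and 2 of 12 amino acid transporters, 1 and 4 of 29 antigen presentation genes, 1 and 4 of 17 NF-kappa-B targets, 7 and 1 of 30 interferon genes and 0 and 4 of 22 apoptosis regulators. Adjusted over the list alone, these counts became 6 and 1, 10 and 1, 2 and 2, 1 and 4, 1 and 4, 7 and 1 and 0 and 4. Of the markers of other cell types, CD4 alone was measured (log2 0.76), a call that ended without untreated footprint library 1.

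Of 11473 genes tested in footprints, 1160 rose, 782 fell and 9531 did not pass. The largest changes included short noncoding RNAs and genes with little RNA. SNORA5C, a small nucleolar RNA, fell from 39.6 ± 10.8 to 4.21 ± 2.03 CPM (log2 −3.20, SE 0.301, adjusted p = 1.16e-06), and TTC34 fell from 35.9 ± 1.13 to 4.06 ± 0.607 CPM (log2 −3.14) with 0.361 CPM in untreated RNA. SEMA3B rose from 3.22 ± 2.37 to 19.6 ± 6.65 CPM (log2 3.08) with 0.386 CPM in untreated RNA. The number of changed genes fell from 1942 to 862 without untreated footprint library 1 and to 1111 without treated footprint library 3. Camera called 12 lists up and 2 down of 26, 0 with an estimated correlation, and fry called 17.

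Translational efficiency asks whether footprints changed more or less than the RNA of the same gene, with the change in the ratio tested as 1 interaction over the 10 libraries. These libraries were scaled together for the test, while CPM values and the separate RNA and footprint changes come from scaling within each assay. A translational efficiency change is therefore not the plain difference of those changes, and its zero point depends on the scaling. The largest RNA polymerase II subunit, POLR2A (ENSG00000181222), rose 3.24-fold (log2 change 1.70, SE 0.214, adjusted p = 9.76e-05), as its RNA went from 54.3 ± 12 to 31.6 ± 4.43 CPM and its footprints from 137 ± 27.6 to 214 ± 10.9 CPM. Its call ended when RNA and footprints of equal number were fitted as 1 culture (log2 1.71, adjusted p = 0.0616). PARP1, a DNA repair enzyme, rose 3.12-fold (log2 1.64, SE 0.209, adjusted p = 0.000103). The selenoprotein gene SEPW1 fell by 1.76 on the log2 scale (SE 0.237, adjusted p = 0.000175), and TMEM167B by 1.26 (SE 0.183, adjusted p = 0.000409). Ribosome biogenesis factors rose in 13 of 55 cases and fell in none (24 and 2 adjusted over the list alone, median 0.44, camera adjusted p = 8.74e-08, adjusted p = 0.605 with an estimated correlation), among them NCL (log2 1.51), TCOF1 (log2 1.30) and NOLC1 (log2 1.24). Translation factors rose in 6 of 46 cases with none lower (12 and 1 adjusted over the list alone, median 0.16, adjusted p = 0.0204, adjusted p = 0.671 with an estimated correlation), and the initiation scaffold EIF4G1 stood at log2 1.20 (adjusted p = 0.00137) with an RNA change of −0.04 that did not pass. Aminoacyl-tRNA synthetases rose in 4 of 22 cases with none lower (13 and 0 adjusted over the list alone, median 0.47, adjusted p = 0.00014, adjusted p = 0.605 with an estimated correlation). Proteins encoded by mitochondrial DNA, whose RNA had fallen, rose in 5 of 13 cases with none lower (9 and 0 adjusted over the list alone, median 0.60, adjusted p = 4.39e-05, adjusted p = 0.605 with an estimated correlation), with MT-ND6 at log2 1.11. MT-RNR2 took a smaller share of treated than of untreated footprint counts. Whether mitochondrial ribosomes were recovered alike in both groups was not tested. Nuclear oxidative phosphorylation genes rose in 3 and fell in 6 of 77 cases (3 and 10 adjusted over the list alone, median −0.26, adjusted p = 9.54e-07, adjusted p = 0.605 with an estimated correlation), with UQCR11 at log2 −0.86 and UQCRQ at −0.78, but the median was 0.06 and adjusted p = 0.957 with an offset for coding length.

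Further lists gained translational efficiency in a minority of their genes. The tricarboxylic acid cycle had 6 of 23 higher (9 adjusted over the list alone, median 0.38, adjusted p = 0.000657), DNA replication 7 of 34 (12 adjusted over the list alone, median 0.22, adjusted p = 0.00129), interferon genes 2 of 32 (8 up and 1 down adjusted over the list alone, median 0.47, adjusted p = 0.00355), chaperones 5 of 24 (8 adjusted over the list alone, median 0.36, adjusted p = 0.00561), glycolysis 1 of 19 (6 adjusted over the list alone, median 0.39, adjusted p = 0.00786) and mitosis 4 of 30 (6 up and 1 down adjusted over the list alone, median 0.32, adjusted p = 0.0121). Splicing factors had 8 of 38 higher and 1 lower (12 and 2 adjusted over the list alone, median 0.31, adjusted p = 0.0156), purine, pyrimidine and one-carbon enzymes 6 of 30 higher (9 up and 2 down adjusted over the list alone, median 0.25, adjusted p = 0.039) and markers of other cell types 1 of 3 (1 adjusted over the list alone, median 1.13, adjusted p = 0.0239). For each of these 9 lists adjusted p = 0.605 with an estimated correlation. Histones had 0 of 28 called by edgeR in either direction (0 adjusted over the list alone, median −0.19, camera adjusted p = 0.0374, adjusted p = 0.806 with an estimated correlation), and their median was 0.05 with an offset for coding length. Examples among these lists are ORC1 (log2 1.29), MCM4 (log2 0.88) and HNRNPM (log2 0.94). The other lists did not pass camera. Of the genes measured in them, 2 rose and 0 fell among 78 cytosolic ribosomal proteins (median 0.04, turning to −0.04 under RLE scaling), 1 and 1 among 76 mitochondrial ribosomal proteins, 5 and 0 among 35 MYC targets (median 0.08, −0.02 under upper-quartile scaling), 1 and 1 among 26 growth-arrest genes and 1 and 0 among 24 stress-response genes (median 0.06, −0.01 under RLE scaling). With an offset for coding length, cytosolic ribosomal proteins passed camera upward (median 0.30, adjusted p = 5.53e-05), as did mitochondrial ribosomal proteins (median 0.18 in place of −0.02, adjusted p = 0.0107). Adjusted over the list alone, without the offset, the counts of these 5 lists were 1 and 0, 1 and 0, 6 and 1, 2 and 1 and 1 and 0. A single amino acid transporter of 12, SLC7A1, rose (log2 0.70), 2 of 38 B cell genes rose, including BANK1 (log2 1.36), and 1 of 29 lysosome genes, TPP1, rose (log2 0.64). One NF-kappa-B target of 20 fell, BCL2L1 (log2 −0.73), which is also the apoptosis regulator of 22 that fell, and 0 of 29 antigen presentation and 0 of 20 cholesterol genes were called. Adjusted over the list alone, the counts were 1 transporter, 3 B cell genes, 0 lysosome genes, 1 NF-kappa-B target, 1 apoptosis regulator, 0 antigen presentation genes and 0 cholesterol genes.

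Translational efficiency changes went with coding length across genes. From the shortest to the longest quintile of 7883 protein-coding genes, with median coding lengths of 549, 1002, 1449, 2121 and 3660 nucleotides, the median log2 change was −0.16, 0.00, 0.07, 0.19 and 0.29. The Spearman correlation across genes, which are not independent replicates, was 0.418, and it was 0.227 for footprints alone and −0.229 for RNA alone. With an offset that removes a length trend from each library, the medians of the 5 groups lay between 0.07 and 0.11. With this offset 670 genes were called, and 575 of the 934 called without it kept their call and direction.

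**Figure D3:**
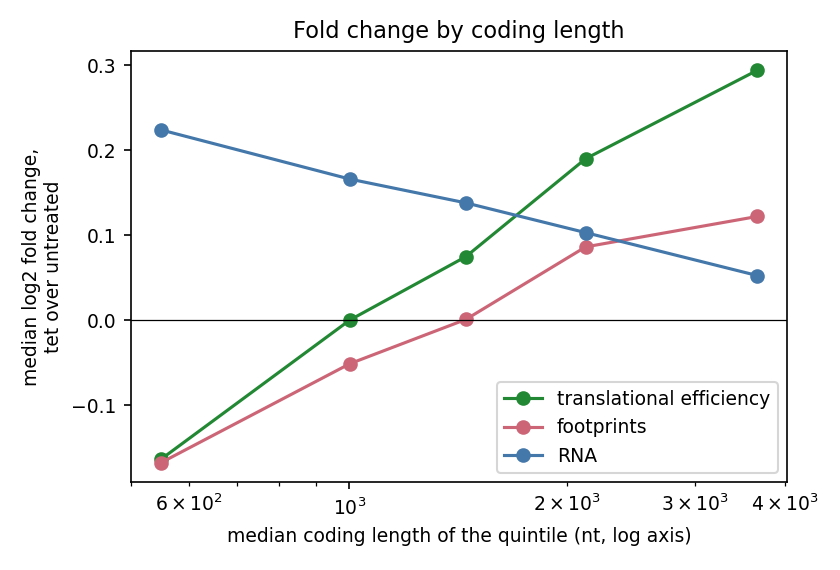
Median log2 change (tetracycline over untreated) in RNA, footprints and translational efficiency by quintile of coding length (x axis, nucleotides), over 7883 protein-coding genes; points are medians of about equal numbers of genes. The translational efficiency median goes from −0.16 in the shortest quintile to 0.29 in the longest.

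Of 14091 genes tested for translational efficiency, 679 rose, 255 fell and 13157 did not pass. RLE scaling gave 471 up and 336 down, and upper-quartile scaling 462 and 363, so the excess of gains was smaller under both. With RNA and footprints of equal number fitted as 1 culture, 888 genes were called, of which 532 were also called above. The number of calls rested on single libraries, and a group left with 1 library was assumed to vary like the others. Without untreated RNA library 1 or 2 the fit called 161 or 143 genes, without treated RNA library 1 or 2 it called 127 or 86, without untreated footprint library 1 it called 257 and without untreated footprint library 3 it called 1415. Of the 79 genes named by rule, 22 kept their call in all 10 of these fits, among them POLR2A, PARP1, SEPW1, TMEM167B, NCL, TCOF1, NOLC1, EIF4G1, MT-ND6, BANK1 and CD4, and the other 57 lost it without treated RNA library 2. The list calls for translation factors, purine enzymes, splicing, mitosis, histones and markers ended in at least 1 of the 10 fits. Camera called 13 lists up and 2 down of 27, 0 with an estimated correlation, and fry called 9.

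The deposited results of the authors address the same change in translational efficiency. In the authors' deposited table POLR2A had a log2 change of 1.59 (adjusted p = 2.43e-07), EIF4G1 one of 1.20 (adjusted p = 6.51e-08) and TMEM167B one of −1.44 (adjusted p = 1.29e-12). For MYC the authors' deposited table lists a translational efficiency change of −0.30 (adjusted p = 0.000244), an mRNA change of −0.17 and a footprint change of −0.48. The authors' deposited table calls 2115 of 10896 tested genes, 585 up and 1530 down, so its split has the opposite sign to the refit with 679 up and 255 down. The refit split depends on scaling, and RLE scaling gave 471 up and 336 down. Among the 10611 genes in both tests, 727 were called by the refit and 2084 in the authors' deposited table, with 541 shared, all in the same direction, against 143 if the calls were independent. Across genes the Spearman correlation of the refit with the authors' deposited table was 0.890 for translational efficiency.

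The 10 libraries with HR in their titles are counted in a pair of separate tables, MycNeg and MycPos, whose columns are named HarPos and HarNeg. They are listed as separate samples. Each HarNeg column correlated most with its own footprint library of the main comparison (Spearman 0.916 to 0.9255 across genes), so shared reads are not excluded. Sample titles and column names pair HR and Har in opposite ways in these tables. HarPos over HarNeg was therefore tested within each table, as the columns are named. An interaction between the tables was added later and also rests on the column names. Library totals were 10204373, 9417886 and 11232461 counts in MycNeg HarNeg, 8780087 and 8435276 in MycNeg HarPos, 8127300 and 7509357 in MycPos HarNeg and 5850088, 9939538 and 7424742 in MycPos HarPos. One unnamed feature, ENSG00000266658, took between 55.7% and 74.9% of the counts of a library, and protein-coding genes took 22.1% to 24.5% in MycNeg HarNeg against 15.3% and 12.2% in HarPos. In MycPos they took 19.4% and 20.5% in HarNeg against 14.1%, 11.4% and 11.8% in HarPos. In the MycNeg table the ribosomal protein RPL22 rose from 12.7 ± 2.11 to 135 ± 9.28 CPM (log2 3.42, SE 0.162, adjusted p = 1.06e-09), and the methylosome protein WDR77 fell from 28.9 ± 3.32 to 4.18 ± 0.3 CPM (log2 −2.78). In the MycPos table SH3RF3-AS1, a long noncoding RNA, rose from 39.7 ± 13.7 to 487 ± 102 CPM (log2 3.62, SE 0.323, adjusted p = 0.000216), and the mitochondrial protein CHCHD2 fell from 51.6 ± 1.23 to 5.00 ± 0.57 CPM (log2 −3.35). MYC had log2 changes of −0.12 (adjusted p = 0.612) in MycNeg and −0.10 (adjusted p = 0.756) in MycPos, neither passing. Tricarboxylic acid cycle genes fell in 18 of 23 cases in MycNeg (18 adjusted over the list alone, median −0.92, adjusted p = 5.19e-09, adjusted p = 0.327 with an estimated correlation) and in 11 of 22 in MycPos (14 adjusted over the list alone, median −0.84, adjusted p = 1.48e-06, adjusted p = 0.654 with an estimated correlation). Aminoacyl-tRNA synthetases fell in 16 of 22 cases in MycNeg (16 adjusted over the list alone, median −0.75, adjusted p = 4.28e-08, adjusted p = 0.327 with an estimated correlation) and in 12 of 22 in MycPos (13 adjusted over the list alone, median −0.74, adjusted p = 3.58e-06, adjusted p = 0.654 with an estimated correlation). Cytosolic ribosomal proteins, which have near-identical copies, rose in 43 and fell in 19 of 78 cases in MycNeg (45 and 19 adjusted over the list alone, median 0.57, adjusted p = 6.08e-09, adjusted p = 0.56 with an estimated correlation) and rose in 24 and fell in 14 in MycPos (28 and 18 adjusted over the list alone, median 0.32, adjusted p = 0.106).

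In all, 1735 features rose and 1865 fell of 11451 tested in MycNeg, and 950 rose and 1140 fell of 10912 in MycPos. Among 10552 features tested in both, 512 rose in both tables against 134 if the calls were independent, and 939 fell in both against 191. Across genes, which are not independent, the Spearman correlation of the changes was 0.746, so columns of the same name moved alike, while the titles pair them the other way. The HarPos effect differed between the tables for 3 of 12118 features by the edgeR interaction, with 917 at an unadjusted p under 0.05. Proteins encoded by mitochondrial DNA rose in 12 of 13 cases in MycNeg (12 adjusted over the list alone, median 0.67, adjusted p = 0.000332, adjusted p = 0.434 with an estimated correlation). In MycPos 0 of 13 were called by edgeR (0 adjusted over the list alone, median 0.15, adjusted p = 0.597). The interaction called 0 of these 13, with camera p = 0.000103 at the preset correlation and 0.234 with an estimated one, neither an exact test. The MycNeg count was 2144 without HarPos library 1, and the MycPos count was 547 without HarNeg library 1 and 137 without HarNeg library 2.

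Predicted open reading frames (ORFs) listed for MycNeg and MycPos address which start sites ribosomes used beyond annotated ones. After repeats were merged, the MycNeg list held 1017 ORFs in 849 genes and the MycPos list 931 in 766 genes, each with a score of at least 0.8 given by the authors. Of these, 361 had identical coordinates in both, which is 35.5% (95% CI 32.5 to 38.5%) of the MycNeg list and 38.8% (35.6 to 42.0%) of the MycPos list. Intervals are exact Clopper-Pearson and cover counting error only. The lists have no replicates, and the 361 shared ORFs count on both sides of each comparison. Fisher's tests therefore describe the lists and do not measure a difference between conditions. ORFs upstream of the annotated coding sequence made up 14.9% (12.8 to 17.3%) in MycNeg and 24.8% (22.1 to 27.7%) in MycPos (Fisher's exact test, two-sided, p = 5.25e-08, Benjamini-Hochberg adjusted p = 2.89e-07 over 11 comparisons). Truncations, which start inside the coding sequence, made up 47.7% (44.6 to 50.8%) and 35.3% (32.3 to 38.5%) (Fisher's exact p = 3.36e-08, adjusted p = 2.89e-07). Starts at ATG made up 16.0% and 21.2% (Fisher's exact p = 0.00415, adjusted p = 0.0152), and starts at CTG 45.7% and 41.6% (p = 0.0675, adjusted p = 0.152). Among the 389 genes with an ORF in both lists the shares of upstream ORFs were 21.98% and 24.36% (Fisher's exact p = 0.412) and of truncations 40.2% and 38.2% (p = 0.562), which did not pass. In these genes 361 of the 505 ORFs of each list are the same ORFs, so the shares were bound to be close.

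Examples in both lists, chosen after the lists were read, show where such ORFs lie, with GRCh37 positions as listed (whether they count from 0 or 1 is not stated). In EIF5, which encodes an initiation factor, an ORF of 98 codons starts at ATG (context GGGTTTATGTCT) at position 103800912 of the plus strand of chromosome 14, ends at 103802261 and overlaps the annotated start. Its scores were 0.990 in MycNeg and 0.995 in MycPos. The transcription factor gene TFAM has a similar overlapping ORF of 100 codons from 60145192 to 60146063 on the plus strand of chromosome 10 (GCGGGCATGATA). HSBP1, which encodes a heat shock factor binding protein, is extended from a CTG (GCCAAGCTGGGC) at 83841666 on the plus strand of chromosome 16, giving an ORF of 82 codons with scores of 0.992 and 0.991. The splicing factor gene U2AF1 has a truncated ORF of 237 codons from a CTG (GAGTATCTGGCC) at 44527591 to 44513210 on the minus strand of chromosome 21. An upstream ORF of 5 codons in ZNF146 starts at ATG (GTTAATATGATC) at 36719654 and ends at 36719669 on the plus strand of chromosome 19. The listed start codon was found at the listed transcript position in 1006 of 1066 MycNeg and 902 of 960 MycPos entries whose transcript was in the reference.

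**Figure D4:**
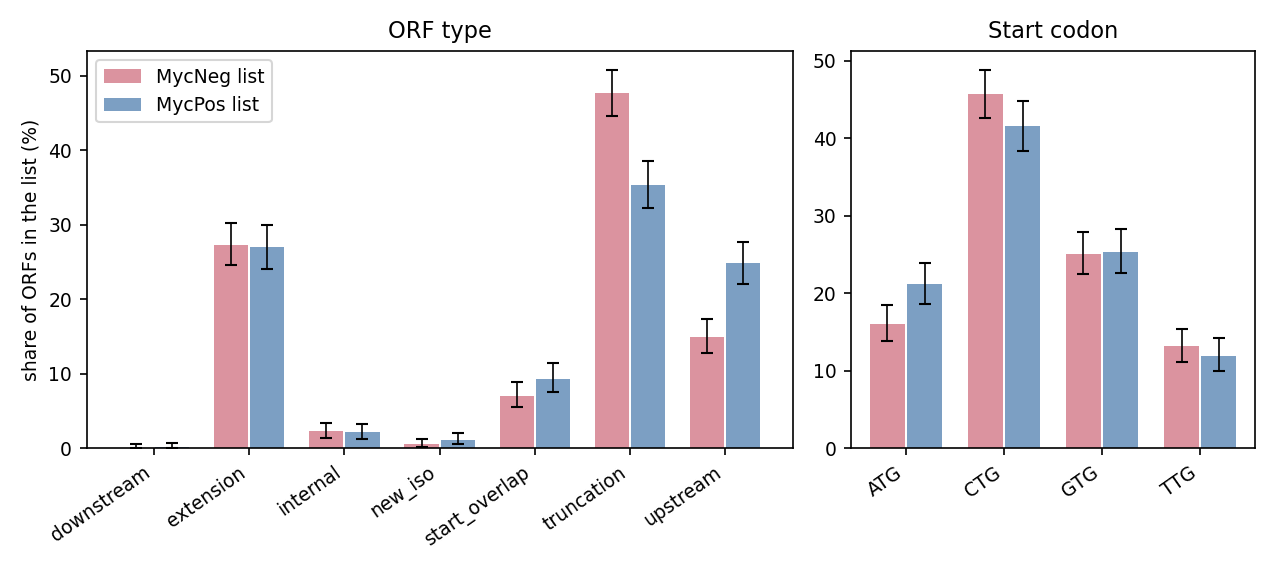
Share of predicted ORFs (percent) by type in the MycNeg list (1017 ORFs) and the MycPos list (931 ORFs), with exact 95% Clopper-Pearson intervals as error bars. Upstream ORFs stand at 14.9% in MycNeg and 24.8% in MycPos, and truncations at 47.7% and 35.3%.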

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

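The tests of exchanged labels and of scaling, and the interaction of HarPos with the table, were chosen after the results they concern were seen. The effect of HarPos over HarNeg differed between the MycNeg and MycPos tables for 3 genes by the edgeR interaction. RBM15B, an RNA-binding protein, had a difference of −2.28 on the log2 scale (SE 0.317, adjusted p = 0.0134), from −0.37 in MycNeg and 1.83 in MycPos. TMEM30B, a flippase subunit, differed by −1.90 (SE 0.312, adjusted p = 0.0394), from 0.15 and 1.96. The collagen gene COL6A1 differed by −2.45 (SE 0.399, adjusted p = 0.0394), from 0.68 and 3.05, with 1.59 CPM in MycPos HarNeg and 13.3 CPM in HarPos. Titles and column names pair HR and Har in opposite ways in these tables, though changes of equally named columns correlated at 0.746 (Spearman, across genes). No explanation of the difference was tested.

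Mitosis and replication genes were higher in the libraries labelled tetracycline, in which MYC is meant to be off. An exchange of labels between the groups would put MYC higher in the treated libraries, but its log2 change was −0.694 in footprints and −0.185 in RNA. These counts add the transgene to the cell's own MYC gene, so the argument holds only for their sum. The choice among the scalings tried is argued against by the mitosis median, whose lowest value over RNA, footprints and these scalings was 1.07. Each of them sets a gene against the rest of its library, so a change in total RNA per cell could not be seen. A biological effect of the treatment stays open as a hypothesis, as do differences between cultures in density or cycle stage, for which the labels give nothing to test. MYC RNA was still 0.880 times the untreated level, so the state of the cells 24 hours after tetracycline may differ from full loss of MYC, which these counts do not resolve.

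Genes of low level were lower in RNA after tetracycline, with 5157 at least 2-fold lower. Greater depth of the untreated libraries is argued against, since 4382 genes were 2-fold lower after these were thinned. Background that is not transcript of the gene, such as genomic DNA, cannot be told apart from lower transcription: summed footprints of these genes had a ratio of 0.287 against 0.401 in RNA, but the footprint ratio was 0.626 without untreated footprint library 2. Olfactory receptor genes, which lymphocytes hardly express, had a count in 310 and 328 of 351 cases in untreated RNA (300 and 317 after thinning) and in 37 and 39 in treated RNA. In footprints 13, 9 and 16 of them had a count without the drug and 12, 13 and 16 with it.

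Changes in translational efficiency went with coding length, at a Spearman correlation of 0.418 across genes. A length trend that differs between single libraries may contribute, as footprint libraries of the same group differed with length at a correlation of up to 0.392 (treated libraries 3 and 1) against 0.211 between groups. This trend as the whole cause is argued against for the genes that kept their call, since 575 of 934 were called the same way with a length offset. A biological dependence on length stays open, as does the call of the other genes and of the oxidative phosphorylation list, which had adjusted p = 0.957 with the offset.

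The 1942 footprint genes were set against other groupings of the 6 libraries. These make 10 splits, too few for a share under 0.05. The real split was the 1 split with as many genes, and the highest of the others called 0. Every other split mixed treated and untreated libraries on both sides, so a difference between the real groups widened the spread within each side. The counts of 0 therefore do not bear on whether the real split arose by accident.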

How the results depend on the processing

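Alternatives with protein-coding genes alone, thinning, the length offset and removal of the top feature were chosen after the data were seen; where no reason is given, the cause was not tested. Against 14246 RNA calls, the stricter filter, which tests fewer genes, called 6448 (4733 shared), the joint fit 3714 (3221 shared), and 5524 had an absolute log2 change of at least 1. For footprints the joint fit called 2974 genes and the minimum change left 610. For translational efficiency DESeq2 called 1976, no filter 1899, only replicate numbers in both assays 1817 and the minimum change 329, while the authors' deposited table calls 2115. MYC in RNA was −0.36 in the joint fit (adjusted p = 0.0657). The estimated correlation left 0 list calls in RNA, 0 in footprints and 0 in translational efficiency, and fry called 9 in translational efficiency, 1 of them, the B cell list, without a camera call. With the length offset, cytosolic ribosomal proteins (adjusted p = 5.53e-05) and mitochondrial ribosomal proteins (adjusted p = 0.0107) reversed, from a downward camera direction that did not pass to higher translational efficiency, with medians of 0.30 and 0.18. At an adjusted p of 0.01, 116 genes were shared with the authors' deposited table, and 220 ORFs over 100 codons were in both lists.

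Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, gave 11431 to 14436 genes in RNA, 862 to 1927 in footprints (862 without untreated library 1, 1111 without treated library 3) and 86 to 1415 in translational efficiency. List calls ranged from 20 to 21 in RNA, 13 to 17 in footprints and 9 to 14 in translational efficiency. MYC ranged from −0.19 to −0.17 in RNA, −0.81 to −0.54 in footprints and −0.41 to −0.16 in translational efficiency. MycNeg ranged from 2144 to 3214 and MycPos from 137 to 2343 features. A replicate block by number gave 13959 RNA genes, 2188 footprint genes, 1413 genes in translational efficiency, 2524 in MycNeg and 2154 in MycPos, and 20, 14 and 15 list calls. In MycPos the numbers came from titles, so the HarNeg library whose column is named Rep3 was blocked under another number. Same-numbered treated and untreated footprint libraries deviated together at r = 0.0148, 0.432 and 0.242, RNA at −0.0712, and RNA with footprints of the same number at −0.0478 and 0.138 (treated) and −0.0664 and −0.199 (untreated), so the numbers were not taken to pair the samples. A replicate block by culture, which takes equal numbers in RNA and footprints as 1 culture, called 888 genes in translational efficiency (726 up, 162 down), of which 532 were among the 934, and POLR2A had adjusted p = 0.0616 in it.

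No named gene changed direction where the main fit or the alternative called it. MYC, not called in MycNeg, went from a log2 change of −0.12 to 0.12 without HarPos library 1. In RNA 1696 of 1727 values stayed on the same side of the threshold, in footprints 1726 of 1874 and in translational efficiency 1341 of 1730. For lists the figures were 162 of 189, 203 of 234 and 324 of 376, with 2 reversed. All 99 values of named genes in MycNeg and 85 of 99 in MycPos stayed on the same side, and CDC42BPB, EMILIN3, INSM1 and OR7G3 lost their MycPos call without HarNeg library 1 or 2. In footprints 75% of simulated 2-fold changes in genes of at least 10 CPM were found, and depth was not separated from the spread between libraries.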

Other observations

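The test of p53 targets was chosen after their RNA values were seen. Targets of p53, the tumour suppressor that halts the cell cycle after damage, were not among the fixed lists, though 9 of the 28 written down are in them. In RNA 17 of 26 measured targets fell and 4 rose, with a median log2 change of −0.40 (camera p = 2.69e-06 at the preset correlation by limma, 0.0843 with an estimated one, neither an exact test). Among those that fell, PLK2 and SPATA18 lay near the floor, at 0.241 and 0.129 CPM in untreated RNA. MDM2, which marks p53 for degradation, fell from 461 to 236 CPM (log2 −0.97, SE 0.0364), and its footprints fell by 1.42 on the log2 scale (SE 0.143). ZMAT3, an RNA-binding target, fell by 0.89 in RNA and 1.51 in footprints, and FDXR, an electron carrier, by 1.12 and 0.99. SESN2 (log2 0.69), DDB2 (log2 0.56), POLH (log2 0.56) and RRM2B (log2 0.27) rose in RNA. These genes were chosen after their values were seen.

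In footprints 9 of 23 p53 targets fell and 2 rose, with a median of −0.448 (camera p = 0.000665 at the preset correlation by limma, 0.0198 with an estimated one, neither an exact test). That p53 activity may be lower after tetracycline is a hypothesis drawn from the 17 lower targets in RNA, which therefore do not test it, and p53 activity itself was not measured.

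Another hypothesis was that an ORF upstream of or overlapping the annotated start, listed with MycNeg alone, goes with lower translational efficiency after tetracycline. The median log2 change was 0.0543 higher, not lower, for the 69 genes with a value listed with MycNeg alone than for the 151 listed with MycPos alone (permutation test, two-sided, p = 0.511), so the test did not meet the prediction.

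Among the 6 footprint libraries of the main table, MycNeg HarNeg libraries 1, 2 and 3 had their highest Spearman correlation across genes, which are not independent, with treated libraries 1, 2 and 3 (0.924, 0.916 and 0.9255). MycPos HarNeg libraries 1 and 2 had theirs with untreated libraries 1 and 3 (0.916 and 0.917). MYC counts in these pairs were 1479 and 1460, 1447 and 1415, 1809 and 1779, 1762 and 1762, and 1458 and 1420. Chi-square over degrees of freedom was 21, 27.7, 30.6, 19.7 and 15.5 in the same pairs. It was lower with another main library for all but the last, but it also depends on depth. The lowest was with the smallest library, untreated library 2, for MycNeg HarNeg 2 (20.5) and 3 (26.9) and MycPos HarNeg 1 (13.7). For MycNeg HarNeg 1 it was with treated library 2 (20.2). MycPos HarNeg library 2 comes from a column named Rep3, so the libraries paired by highest correlation all share treatment and column number. These values do not settle whether the pairs hold the same reads. The HarNeg libraries may therefore not be independent of the main footprint libraries. Genes of nuclear oxidative phosphorylation held predicted ORFs in 26 cases in MycNeg and 28 in MycPos, of which 20 were in both. Mitochondrial DNA-encoded proteins and NF-kappa-B targets held 0.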
